A study of Mus musculus with 16 samples.

How the data were processed

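Lumbar dorsal root ganglia from the side of the injected ankle were sampled, per the labels' protocols, from C57BL/6 wild-type (WT) mice and from knock-in (KI) mice that the labels name TrkA/C. The construct itself is not described in the labels. Mice aged 10 to 12 weeks received vehicle or complete Freund's adjuvant (CFA, a suspension that provokes lasting joint inflammation) into the ankle joint, and ganglia were taken 14 days later. Each of the 16 libraries pooled 6 ganglia from 2 mice, which gave 4 groups of 4 libraries. Groups came from the sample titles. WT CFA replicate 1 carries a knock-in genotype tag against its title, and its Ntrk3 level is reported first for that reason.

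Per the labels' protocols, libraries were made from 150 ng of total RNA by poly-A selection with a kit that selects the sequenced strand, amplified over 15 PCR cycles, and read as single ends of 50 nucleotides. The run held 20 libraries on 3 lanes, and the labels do not tie libraries to lanes, so no sequencing batch could be tested. Per the submitters' processing notes, the tools were bcl2fastq 2.20, FastQC, TopHat2 2.1.1, Bowtie2 2.3.5.1, SAMtools 1.5 and HTSeq 0.6.1p1 with build mm10. Settings, strand mode and annotation are not given there, so reads of genes that overlap or lie antisense to each other cannot be separated here. The deposited values are raw read counts per gene, whole numbers that the authors did not normalize.

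The deposited count table had 24982 gene entries, of which 4755 had 0 counts in every library. The 28 entries with no gene identifier (0.192% of counts) stayed in the counts and were left out only of the match that follows. Entrez identifiers were matched to a reference table of the same build for positions and names (24891 of 24954, 99.7%). The total count per library ran from 22742209 to 40910947. A count of 3 equals 0.132 CPM (a gene's counts divided by the library total, times 1e6) in the shallowest library and 0.0733 CPM in the deepest. It is given as a scale for low counts, and no gene was filtered at it. PCR duplicates cannot be recognized in a count table, so intervals on counts cover counting error only.

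Differences were tested with edgeR 4.0.16 in R 4.3.3. A quasi-likelihood model with 1 mean per group was fitted to all 16 libraries with TMM factors, after filterByExpr left 15507 genes. The common biological coefficient of variation was 11.8%. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and "edgeR adjusted p" below means that value. Log2 fold changes are given ± SE, and CPM values are TMM-normalised, with group means given ± SD with n = 4. The CPM of single neutrophil, marrow and erythroid genes in the closing part use the library total without TMM factors. Log2 CPM used a prior count of 2. The 7 comparisons were KI against WT with vehicle, with CFA and as the mean of both, CFA against vehicle in WT, in KI and as the mean of both, and the interaction of genotype and injection. The 4 against 4 design allows an exact permutation p of 0.0286 at the smallest.

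Gene lists were fixed before the data were examined, and 34 of 36 had at least 3 tested members. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over all lists by Benjamini-Hochberg, and again with an estimated correlation, which is the stricter of the tests here. List counts are given over all genes tested and adjusted over the list alone. Some genes stand on more than 1 list, such as Calca and Gal. List scores per library are mean log2 CPM.

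The rule for named genes was also fixed before the data were examined. It took genes set by the design, such as Ntrk3, the 12 largest rises and 12 largest falls among called genes with a mean of at least 1 CPM and groups that do not overlap, the 5 smallest p-values, and at most 4 members per list with the smallest p. Where fewer than 10 genes passed, it took the 10 smallest p-values. The rule gave more genes than the text names, and some results are not reported here. Among its list members, the lists shown and the examples from them were picked after their values had been seen. Pvalb, Nmb, Cartpt, Bmpr1b, Sstr2, Oprk1, Sox11, Psmb9 and the muscle, marrow and erythroid genes given as context were also named after their values were seen, where the rule did not give them. All items of the rule's first parts, and all list members considered for the text, entered the alternatives, whether or not their calls held.

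The alternatives fixed beforehand were other size factors, other filters, DESeq2 1.42.0, limma-voom with quality weights, robust dispersion, a fit of only the groups compared, a replicate block, other thresholds, leaving out each library in turn, and leaving out lists of adjacent tissue. Those added after the data were seen were the skeletal muscle score as a covariate, 2 surrogate variables (sva 3.50.0), a split of the WT libraries as a covariate, and fits without 2 or 6 libraries. The WT split was not centred, so WT stands there at its fitted level in replicates 1 and 2. Genotype values with that covariate compare KI with this level, not with the mean of all WT libraries. The steps were tested on simulated counts with known changes, in a single run per comparison. Each run changed 50 genes at each of 1.25, 1.5, 2 and 4-fold, all with a mean of at least 1 CPM. Genes were drawn independently of each other. Planted changes ease the adjusted threshold, so the shares recovered can overstate what a comparison with few real changes would find. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.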

Results

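Gene expression was measured by RNA sequencing in lumbar dorsal root ganglia of wild-type (WT) and TrkA/C knock-in (KI) mice, 14 days after vehicle or CFA was injected into the ankle joint. There were 4 libraries in each of the 4 groups, and each library pooled ganglia of 2 mice. Library totals ran from 22742209 to 31816832 counts in WT vehicle, from 28490746 to 34348881 in WT CFA, from 27698035 to 37576008 in KI vehicle and from 31238001 to 40910947 in KI CFA. Libraries are named below by group and replicate number.

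Ntrk3 was read first in every library. This gene, which encodes TrkC (Entrez 18213, chromosome 7, 78179986 to 78581034, build mm10), was higher in all 8 KI libraries than in any WT library. Its mean was 45.0 ± 11.4 CPM (SD, n = 4) in WT vehicle, 49.9 ± 7.89 in WT CFA, 122 ± 13.2 in KI vehicle and 109 ± 9.18 in KI CFA. Single WT libraries lay between 29.3 and 61.4 CPM and single KI libraries between 99.1 and 138. WT CFA 1, whose genotype tag reads knock-in, had 48.4 CPM and lay with the other WT libraries.

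**Figure D1:**
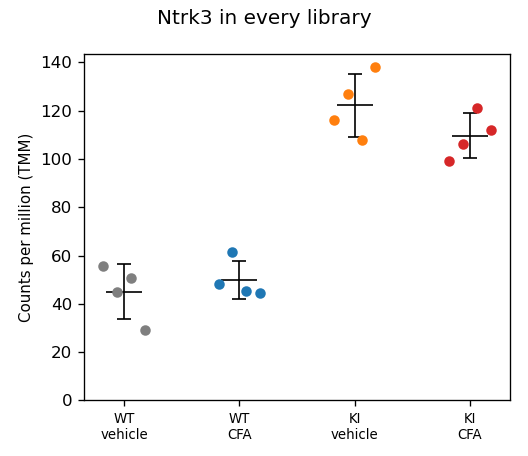
Ntrk3 in CPM (TMM) for each of the 16 libraries, by group, with a line at the mean and bars of 1 SD. Ntrk3 lies between 29.3 and 61.4 in WT and between 99.1 and 138 in KI libraries.

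The first comparison asked how the ganglia of KI mice differ from WT without joint inflammation. At the preset correlation, lists of peptidergic nociceptor, neuropeptide and regeneration transcripts lay lower in KI, and lists that mark large A-fibre neurons and non-peptidergic nociceptors lay higher. None of these 5 lists held with an estimated correlation, and in each a part of the members passed as single genes. Of 15507 genes, edgeR called 673, of which 333 rose and 340 fell. Most changes were small, with 111 rises and 63 falls of at least 1.5-fold. DESeq2 called 1476 genes and limma-voom 799. Leaving out 1 library gave from 284 to 905 calls, and the count dropped more than 1.5 times without KI vehicle 1 (354), 2 (408), 3 (410) or 4 (284) and without WT vehicle 3 (367) or 4 (401).

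Ngfr, the neurotrophin co-receptor p75 (chromosome 11, 95568818 to 95587698), fell by 0.59 ± 0.06 on the log2 scale (edgeR adjusted p = 2.24e-05). Ntrk3 rose by 1.44 ± 0.15 (edgeR adjusted p = 3.94e-05). The neurotrophin list had 3 members that rose, 3 that fell and 9 not called, with Gfra3 among the falls (-0.58 ± 0.08). Of the 12 peptidergic markers, 8 fell, 1 rose and 3 were not called; adjusted over the list alone 9 fell and 1 rose. Smr2 fell strongly (-2.03 ± 0.19, edgeR adjusted p = 2.18e-05), and Calca (chromosome 7, 114625981 to 114636910) fell by 0.91 ± 0.13 (edgeR adjusted p = 0.000735). Adcyap1 (-0.47), Tac1 (-0.57), Trpv1 (-0.45) and Bmpr1b (-0.50) fell too, while Sstr2 rose (0.35). The median of the list was -0.48 (camera adjusted p = 6.33e-11; adjusted p = 0.0596 with an estimated correlation). Of 16 neuropeptide and opioid genes, 6 fell and 10 were not called, and 7 fell adjusted over the list alone. Gal fell by 1.27 ± 0.22, and Cartpt (-0.93) and Nmb (-0.44) fell with it. That list had a median of -0.40 (camera adjusted p = 0.000166; adjusted p = 0.158 with an estimated correlation).

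Of the 15 A-fibre markers, 5 rose and 10 were not called, and 6 rose adjusted over the list alone. Besides Ntrk3 these were Whrn (0.89 ± 0.15), Pvalb (0.81), Runx3 (0.77 ± 0.14) and Etv1 (0.58 ± 0.09). The list median was 0.20 (camera adjusted p = 3.72e-07; adjusted p = 0.158 with an estimated correlation). Of the 11 non-peptidergic markers, 4 rose and 7 were not called, and 6 rose adjusted over the list alone. Mrgprd (0.35 ± 0.07) and Plxnc1 (0.35 ± 0.07) rose, as did Scn11a (0.33) and Gfra2 (0.35). The call of Scn11a ended without KI vehicle 1 (0.31), and that of Gfra2 without KI vehicle 1 (0.30), 3 (0.34) or 4 (0.37) or WT vehicle 3 (0.38); without WT vehicle 4 Gfra2 was still called, at 0.23. The list median was 0.23 (camera adjusted p = 3.85e-05; adjusted p = 0.219 with an estimated correlation). Of the 30 sensory ion channels, 5 fell, 1 rose and 24 were not called; 6 fell and 8 rose adjusted over the list alone. The falls included Kcnk2 (-0.63), Kcnk4 (-0.55 ± 0.11) and Asic3 (-0.39 ± 0.07). Of 21 axon injury and regeneration genes, 4 fell and none rose, also adjusted over the list alone. Gap43 fell by 0.69 ± 0.08 (edgeR adjusted p = 8.43e-05) and Stmn4 by 0.52 ± 0.11. Hspb1 fell by 0.37, a call that ended without KI vehicle 4 (-0.32). The list median was -0.25 (camera adjusted p = 0.00426; adjusted p = 0.714 with an estimated correlation). It moved to -0.16 without KI vehicle 1, -0.39 without KI vehicle 3, -0.08 without WT vehicle 2 and -0.12 without WT vehicle 4.

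Outside the lists, the gene with the 5th smallest p was Pcp4l1, which fell by 0.77 ± 0.08 (edgeR adjusted p = 3.94e-05). Rxfp1 rose by 1.33 ± 0.18 (edgeR adjusted p = 0.00061) and Bmp3 by 1.12 ± 0.23. Gabrg3 fell by 1.24 ± 0.24, and Fos fell by 0.84 ± 0.18. Hc (-1.77), Ccer2 (-2.30), Gm7714 (-2.54) and Gm13848 (-1.11) were also among the largest falls. Several of the other large changes were no longer called when single libraries were left out. The fall of Fgg ended as a call without KI vehicle 4 (-1.35) or WT vehicle 4 (-1.13), that of B230216N24Rik without KI vehicle 2 (-1.61) or WT vehicle 4 (-1.60), and that of Mymk without KI vehicle 1 (-1.48) or 4 (-1.57) or WT vehicle 3 (-1.51) or 4 (-1.41). That of D330050G23Rik ended without KI vehicle 1 (-1.13), 3 (-0.97) or 4 (-1.05) or WT vehicle 3 (-1.10) or 4 (-1.01). The rise of Acrbp ended as a call without KI vehicle 1 (1.10) or 4 (1.08) or WT vehicle 1 (0.99) or 4 (1.06). That of Lrrc7 ended without any KI vehicle library but replicate 3, any WT vehicle library, KI CFA 2 or WT CFA 1 or 4 (1.04 to 1.32).

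Part of the largest rises were skeletal muscle transcripts, which differed between single libraries. The mean log2 CPM of the muscle list was 6.07 in KI vehicle 1, 3.02 in KI vehicle 3 and 6.25 in KI vehicle 4, against 1.55 in WT vehicle 1, 2.62 in WT vehicle 4, 2.27 in KI CFA 2 and at most 0.52 in the other 10. Ryr1 rose by 3.31 ± 0.60, Cmya5 by 2.36 ± 0.44 and Myom1 by 2.02 ± 0.39. Of the 11 muscle markers, 3 rose, and 11 rose adjusted over the list alone. Those 3 were Myh2 (5.66), Acta1 (3.98) and Mylpf (3.53), and none of these calls held when single libraries were left out. The call of Myh2 ended without KI vehicle 4 (3.15) or WT vehicle 1 (5.48), 2 (5.26) or 3 (5.50). Mylpf lost it without KI vehicle 1 (3.08) or 4 (3.04) or WT vehicle 1 (3.58), 2 (3.22) or 3 (3.22), and Acta1 without any library but KI CFA 2 or 4, KI vehicle 2 or 3 or WT vehicle 4 (3.33 to 4.08). Trim72 lost its call without KI vehicle 1 (2.38) or 4 (2.24), Dusp27 without KI vehicle 4 (1.01) or WT vehicle 4 (0.99), and Itga10 without KI vehicle 3 (1.24) or 4 (1.59) or WT vehicle 1 (1.49). Ppp1r3a lost it without any library but KI CFA 2 or 4, KI vehicle 2 or 3 or WT CFA 3 (1.20 to 1.69). The median of the muscle list was 3.87 (camera adjusted p = 0.00127; adjusted p = 0.714 with an estimated correlation), and without WT vehicle 2 it was 3.45 and not called. With the muscle score as a covariate, 349 genes were called and 330 of them were among the 673.

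Ribosomal protein transcripts moved with WT vehicle 4, whose list score was 7.19 against 6.55 to 6.81 in the other 15 libraries. Of 46 ribosomal genes, 2 fell, Rpl3 (-0.22) and Rpl6 (-0.20), and 38 fell adjusted over the list alone, with a median of -0.24 (camera adjusted p = 1.46e-13; adjusted p = 0.675 with an estimated correlation). Without WT vehicle 4 the median was -0.11, Rpl3 and Rpl6 were both at -0.16, and neither was called. Rpl3 also lost its call without any KI vehicle library or WT vehicle 3 (-0.23 to -0.21), and Rpl6 without any KI library, WT CFA 1 or 3 or WT vehicle 3 (-0.23 to -0.19). Among 25 nuclear oxidative phosphorylation genes only Ndufb3 fell (-0.41 ± 0.08), and the median was -0.17 (camera adjusted p = 2.34e-05; adjusted p = 0.714 with an estimated correlation), which was -0.08 without WT vehicle 4.

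The second comparison asked how the genotypes differ under joint inflammation. The medians of the same lists had the same signs as with vehicle. Here the peptidergic, neuropeptide and A-fibre lists held with an estimated correlation, and the non-peptidergic and regeneration lists did not. edgeR called 441 genes, of which 169 rose and 272 fell, with 71 rises and 101 falls of at least 1.5-fold. DESeq2 called 667 and limma-voom 636. Leaving out 1 library gave from 241 to 652 calls, and the count dropped more than 1.5 times without KI CFA 2 (267) or 3 (241) or WT CFA 2 (289).

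Ngfr fell by 0.75 ± 0.06 (edgeR adjusted p = 7.18e-07) and the nicotinic receptor gene Chrna7 by 0.87 ± 0.07 (edgeR adjusted p = 7.61e-07). Prokr2 fell by 1.3 ± 0.11 and Nptx1 by 0.64 ± 0.06. Ntrk3 rose by 1.13 ± 0.14 (edgeR adjusted p = 0.000249). Of the 12 peptidergic markers, 8 fell and 1 rose, and 10 fell and 1 rose adjusted over the list alone. Smr2 (-1.99 ± 0.19), Adcyap1 (-0.63 ± 0.08), Trpv1 (-0.59 ± 0.09), Calca (-0.71 ± 0.13) and Bmpr1b (-0.70) fell, and Sstr2 rose (0.53). The list median was -0.55 (camera adjusted p = 4.50e-18; adjusted p = 0.00728 with an estimated correlation). Of 16 neuropeptide and opioid genes, 7 fell and 9 were not called, and 8 fell adjusted over the list alone. Gal (-1.20 ± 0.22), Cartpt (-1.04), Oprk1 (-1.02) and Oprm1 (-0.57 ± 0.12) were among them, and the list median was -0.52 (camera adjusted p = 2.98e-09; adjusted p = 0.0169 with an estimated correlation). Of the 15 A-fibre markers, 8 rose and 7 were not called; adjusted over the list alone 10 rose and 1 fell. Pvalb (1.05), Whrn (0.97 ± 0.15), Runx3 (0.94 ± 0.14) and Etv1 (0.54 ± 0.09) rose, and the list median was 0.32 (camera adjusted p = 1.27e-09; adjusted p = 0.0427 with an estimated correlation).

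Of the 11 non-peptidergic markers, 2 rose, and 3 rose adjusted over the list alone, with a median of 0.18 (camera adjusted p = 5.73e-06; adjusted p = 0.134 with an estimated correlation). Mrgprd (0.29) was among the 2, and its call ended without KI CFA 3 (0.25) or WT CFA 1 (0.30), 3 (0.28) or 4 (0.28). Of the 30 ion channels, 5 fell and 3 rose; Kcnk2 fell by 0.86 ± 0.17 and Asic3 by 0.41 ± 0.07. Kcns1 rose (0.32), a call that ended without KI CFA 2 (0.27) or 3 (0.29). Of 21 injury and regeneration genes, 4 fell, and 10 fell adjusted over the list alone, with a median of -0.37 (camera adjusted p = 1.77e-07; adjusted p = 0.225 with an estimated correlation). The list score was 4.305 in WT CFA 1 and 4.222 in WT CFA 2, but 3.155 and 3.202 in WT CFA 3 and 4 and 3.044 to 3.302 in the KI CFA libraries. Gap43 (chromosome 16, 42248552 to 42340651) fell by 0.79 ± 0.08 (edgeR adjusted p = 1.21e-05) and Stmn4 by 0.70 ± 0.11. Jun fell by 0.37, a call that ended without KI CFA 2, 3 or 4, KI vehicle 3 or WT CFA 1, 2 or 3 (-0.37 to -0.32). Of 12 MAPK feedback genes, 2 fell. Etv5 fell by 0.44 ± 0.08 (edgeR adjusted p = 0.00292), and Spred3 fell by 0.36, a call that ended without any KI CFA library but replicate 4 or without any WT CFA library (-0.38 to -0.30).

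Outside the lists, the largest rises included Rxfp1 (1.63 ± 0.19), Calb2 (1.44 ± 0.28), Ctgf (1.32 ± 0.26), Wdr72 (1.21 ± 0.16) and Vstm2b (1.20 ± 0.18). The largest falls included Tmc5 (-1.84), Mymk (-1.81), Gabrg3 (-1.69 ± 0.25), C1qtnf7 (-1.60 ± 0.24), Mrap2 (-1.52 ± 0.26) and Slc5a7 (-1.48 ± 0.23). Irx6 fell by 1.87, a call that ended without KI CFA 3 (-1.73). The rise of Stra6 ended as a call without KI CFA 1 (1.18) or 2 (1.36) or WT CFA 2 (1.41), that of Trim59 without WT CFA 2 (1.12), and that of Pln without KI CFA 3 (0.91) or WT CFA 2 (1.08) or 3 (1.03). Gjb2 lost its call without any KI CFA library but replicate 4 or any WT CFA library but replicate 1 (0.99 to 1.26). Sfmbt2 lost it without KI CFA 2 or 3 or any WT CFA library but replicate 2 (1.02 to 1.16), and Dppa2 kept it only without KI CFA 1, KI vehicle 2 or 4, WT CFA 4 or WT vehicle 4 (-2.04 to -1.44 without any of the others).

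At the preset correlation, the lists of interferon-stimulated and antigen presentation transcripts lay lower in KI CFA than in WT CFA. Neither held with an estimated correlation, and the 3 genes of them that passed all lost the call without WT CFA 2. The interferon list score was 4.26 in WT CFA 2 and 3.55 in WT CFA 3, against 2.65 to 3.17 in the other 14 libraries. Of 32 interferon-stimulated genes, 2 fell, and 19 fell adjusted over the list alone, with a median of -0.58 (camera adjusted p = 5.64e-12; adjusted p = 0.379 with an estimated correlation). That median was -0.23 without WT CFA 2. Without WT CFA 2, Igtp went from -0.56 to -0.39, Oasl2 from -0.58 to -0.35 and the antigen presentation gene Nlrc5 from -0.82 to -0.48, and none was called. Igtp also lost its call without KI CFA 2 or 3 or WT CFA 3 (-0.53 to -0.48). Oasl2 kept it only without KI vehicle 2, WT CFA 1 or 4 or WT vehicle 4, and Nlrc5 only without KI CFA 4, KI vehicle 2, WT CFA 1 or 3 or WT vehicle 4. Of the 16 antigen presentation genes, 1 fell, and 8 fell adjusted over the list alone (median -0.33, camera adjusted p = 7.34e-09; adjusted p = 0.125 with an estimated correlation). No neutrophil marker was called over all genes, 10 of 12 rose adjusted over the list alone, and the median of 2.25 (camera adjusted p = 0.00905; adjusted p = 0.765 with an estimated correlation) became 0.04 without KI CFA 3 and 1.97 without WT CFA 4, and was called in neither case. The muscle list had a median of 4.46 (camera adjusted p = 0.0039; adjusted p = 0.765 with an estimated correlation), and without KI CFA 2 it was 3.29 and not called.

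**Figure D2:**
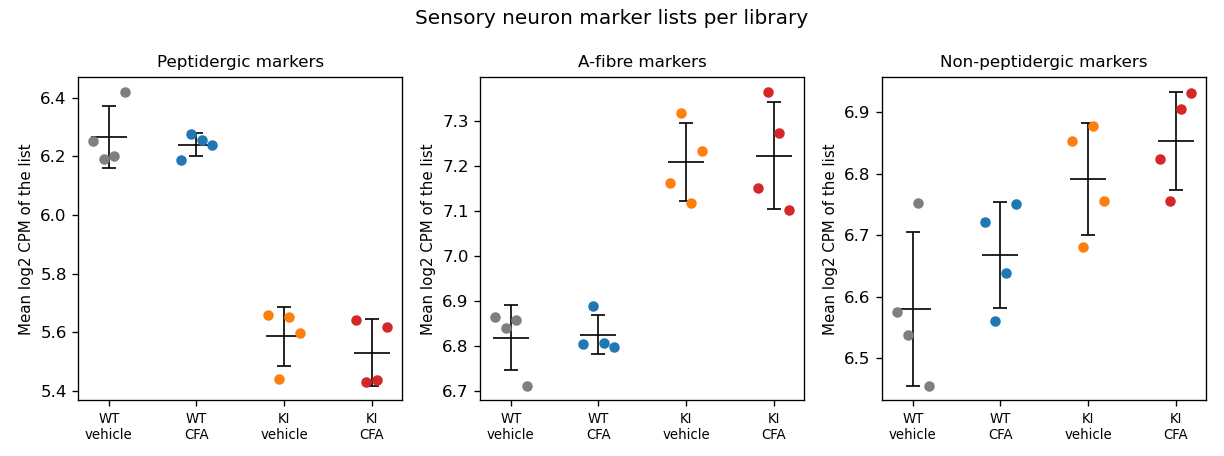
Mean log2 CPM of the peptidergic, A-fibre and non-peptidergic marker lists in each of the 16 libraries, by group, with a line at the mean and bars of 1 SD. The list medians of KI against WT are -0.48, 0.20 and 0.23 with vehicle and -0.55, 0.32 and 0.18 with CFA.

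The genotype differences measured with vehicle and with CFA come from separate libraries and can be set side by side. Of the called genes, 90 rose in both and 148 fell in both, where independent lists would share 3.63 and 5.96, and 0 went in opposite directions. A further 435 genes were called with vehicle only and 203 with CFA only. Of the 673 genes called with vehicle, 94.1% had the same sign with CFA, and of the 441 called with CFA, 97.5% had the same sign with vehicle. Across all genes the Pearson correlation of the fold changes was 0.455, with genes that are not independent replicates.

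**Figure D3:**
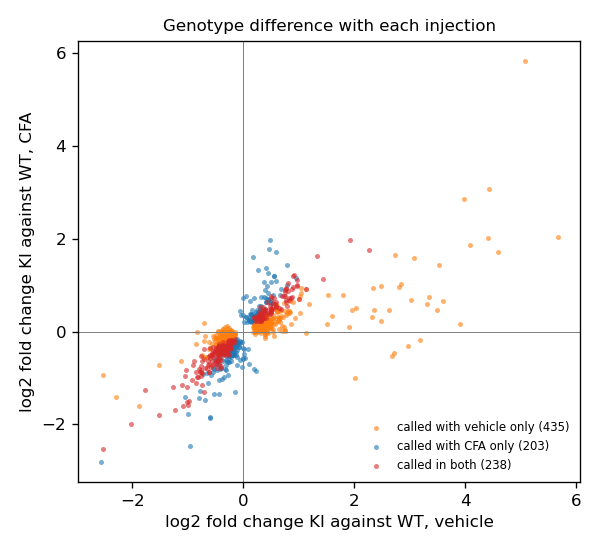
Log2 fold change of KI against WT with vehicle (horizontal) and with CFA (vertical) for each called gene, coloured by where edgeR called it. All 238 genes called in both lie in the quadrants of equal sign.

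The mean genotype difference over both injections used 8 against 8 libraries and asked what the knock-in changes whatever the injection. The peptidergic, A-fibre and neuropeptide lists held here with an estimated correlation too. edgeR called 1390 genes, of which 671 rose and 719 fell, with 140 rises and 114 falls of at least 1.5-fold. Leaving out 1 library gave from 993 to 1430 calls. Ngfr fell by 0.67 ± 0.04 (edgeR adjusted p = 1.39e-08), Chrna7 by 0.75 ± 0.05 (edgeR adjusted p = 2.84e-08), and Smr2 fell by 2.01 ± 0.13 (edgeR adjusted p = 4.14e-08) and Nptx1 by 0.57 ± 0.04 (edgeR adjusted p = 6.86e-08). Ntrk3 rose by 1.29 ± 0.10 and Rxfp1 by 1.48 ± 0.13, followed by Wdr72 (1.06), Vstm2b (1.05), Pln (1.04), Bmp3 (1.02) and Pcdh8 (0.98 ± 0.11). Muscle transcripts were higher here too, with the muscle list called at the preset correlation and Myom1 called as a gene. With the muscle score as a covariate the list (median 0.47) and Myom1 (0.61) lost the call. Of the 12 peptidergic markers, 9 fell and 1 rose, and 10 fell and 1 rose adjusted over the list alone (median -0.54, camera adjusted p = 2.94e-14; adjusted p = 0.0195 with an estimated correlation). Of the 15 A-fibre markers, 10 rose and 1 fell, also adjusted over the list alone (median 0.26, camera adjusted p = 2.65e-09; adjusted p = 0.0449 with an estimated correlation). Of 16 neuropeptide and opioid genes, 9 fell and none rose, and 10 fell adjusted over the list alone (median -0.36, camera adjusted p = 2.26e-07; adjusted p = 0.0383 with an estimated correlation). Of the 11 non-peptidergic markers, 7 rose, and 8 rose adjusted over the list alone (median 0.25, camera adjusted p = 9.75e-07; adjusted p = 0.108 with an estimated correlation). Trpv1 (-0.52), Kcnk4 (-0.52 ± 0.07), Kcnk2 (-0.74 ± 0.12) and Asic3 (-0.40) fell among the ion channels. Gap43 (-0.74), Stmn4 (-0.61) and Gal (-1.24) fell among the injury genes, where 4 fell, 6 fell adjusted over the list alone, and the median was -0.37 (camera adjusted p = 9.96e-06; adjusted p = 0.449 with an estimated correlation).

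The comparison of CFA with vehicle in WT asked what joint inflammation changes in the ganglia 14 days later. No gene passed. edgeR called 0 genes with a smallest adjusted p of 0.141, while 1079 genes had an unadjusted p under 0.05, DESeq2 called 11 and limma-voom 1. On simulated data with 156 genes called, the same comparison recovered 80% of changes of 1.5-fold and 30% of changes of 0.32 on the log2 scale. With 0 real calls the adjusted threshold was stricter, so these shares can overstate what the real comparison would find. Among the genes with the smallest p were Sbno2 (0.29 ± 0.05), Pappa (0.91), Ptpn9 (0.26), Prokr2 (0.56), Tap1 (0.93), Ahr (0.36), Tfrc (0.40), Fam222a (0.56) and Irgm2 (0.79). edgeR called none of these 9, while DESeq2 called all 9 and limma-voom called Sbno2. When 1 library was left out, edgeR called Tap1 (1.09) and Tfrc (0.48) without WT CFA 1 and no other gene of these without any other library. Interferon-stimulated transcripts were higher in WT CFA 2 and 3, as given above. Iigp1 (1.77 ± 0.42), Igtp (0.53) and Psmb9 (0.77) lay above vehicle on average and were not called. Adjusted over the list alone, 26 of 32 interferon-stimulated genes rose, with a median of 0.70 (camera adjusted p = 6.92e-24; adjusted p = 0.286 with an estimated correlation) that was 0.35 without WT CFA 2. Adjusted over the list alone, 6 of 16 antigen presentation genes rose (median 0.23, camera adjusted p = 7.32e-08; adjusted p = 0.286 with an estimated correlation). The ribosomal list had a median of -0.15 (camera adjusted p = 1.38e-12; adjusted p = 0.558 with an estimated correlation), which was -0.03 without WT vehicle 4. The oxidative phosphorylation median was -0.12 (camera adjusted p = 1.71e-06; adjusted p = 0.558 with an estimated correlation), and -0.03 without WT vehicle 4. Adjusted over the list alone, 3 of 21 injury genes rose (median 0.11, camera adjusted p = 0.00473; adjusted p = 0.598 with an estimated correlation). That median was 0.07 without WT CFA 1, 0.08 without WT CFA 2 and 0.06 without WT vehicle 1, where the list was not called, and 0.19 without WT vehicle 4. Jun (0.37), Sox11 (0.55) and Ntrk3 (0.15) were not called.

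In KI mice the same comparison asked what inflammation changes in the knock-in. No gene passed. edgeR called 0 genes with a smallest adjusted p of 0.247, while 881 genes had an unadjusted p under 0.05, DESeq2 called 15 and limma-voom 0. Without KI vehicle 2, the library of that group with little muscle signal, 53 genes were called. Simulated changes of 1.5-fold were recovered in 78%, with the same limit as in WT. Most of the genes with the smallest p belong to muscle and follow the muscle libraries of KI vehicle. These were Txlnb (-2.93), Ryr1 (-2.97), Neb (-3.03), Cmya5 (-2.05), Pygm (-3.06), Trim72 (-2.78), Myo18b (-3.12) and Myom2 (-3.64), with Rasa4 (0.38) and Ildr2 (-0.37). edgeR called none of these 10, while DESeq2 called all 10. Adjusted over the list alone, 11 of 11 muscle markers fell (median -4.59, camera adjusted p = 2.50e-09; adjusted p = 0.884 with an estimated correlation). Adjusted over the list alone, 10 of 12 neutrophil markers rose (median 2.47, camera adjusted p = 1.88e-05; adjusted p = 0.948 with an estimated correlation), with a list score of 3.93 in KI CFA 3 and at most 1.34 in the other 15 libraries. Without KI CFA 3 that median was 0.38 and not called.

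**Figure D4:**
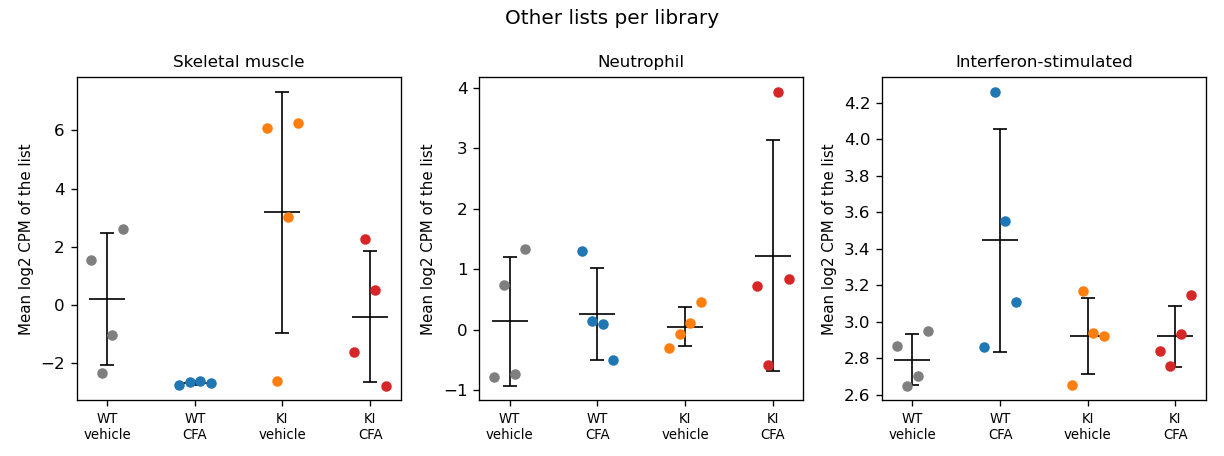
Mean log2 CPM of the skeletal muscle, neutrophil and interferon-stimulated lists in each of the 16 libraries, by group, with a line at the mean and bars of 1 SD. The top scores are 6.25 and 6.07 for muscle (KI vehicle 4 and 1), 3.93 for neutrophils (KI CFA 3), and 4.26 and 3.55 for interferon (WT CFA 2 and 3).

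The mean effect of CFA over both genotypes used 8 against 8 libraries. Small rises were called in 4 genes and no fall was called. edgeR called Tfrc, the transferrin receptor (0.37 ± 0.06, edgeR adjusted p = 0.0337), Sbno2 (0.22 ± 0.03, edgeR adjusted p = 0.0337), Rasa4 (0.35 ± 0.06, edgeR adjusted p = 0.0337) and Ptpn9 (0.21 ± 0.04, edgeR adjusted p = 0.0433). DESeq2 called 57 genes and limma-voom 7. Cyp26b1 (-0.57 ± 0.10), Serinc2 (0.23), Ecm2 (-0.74), Scg3 (0.19), 9430021M05Rik (0.34) and Hic1 (-0.71) followed by p and were not called by edgeR. DESeq2 called all 6 of these, limma-voom called Cyp26b1 and Serinc2, and edgeR with robust dispersion called Cyp26b1. The 4 edgeR calls lay near the threshold, and most ended when 1 library was left out, while the changes moved little. Where a call ended that way, Tfrc lay at 0.33 to 0.38, Sbno2 at 0.20 to 0.23, Rasa4 at 0.31 to 0.36 and Ptpn9 at 0.19 to 0.22. The count was 39 without KI vehicle 2, 7 without KI CFA 1, 5 without WT vehicle 4, 2 without WT CFA 1, 1 without WT vehicle 2 and 0 without any other single library. Interferon-stimulated genes had a median of 0.32 (camera adjusted p = 1.34e-14; adjusted p = 0.705 with an estimated correlation), which was 0.17 without WT CFA 2.

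The interaction asked whether the response to CFA differs between the genotypes. No gene passed. edgeR called 0 genes with a smallest adjusted p of 0.718, while 976 genes had an unadjusted p under 0.05 and DESeq2 and limma-voom called 0 each. Simulated interactions of 2-fold were recovered in 82%, those of 1.5-fold in 64% and those of 0.32 on the log2 scale in 8%. The limit given for the simulation of CFA in WT applies to these shares too. The smallest p-values belonged to Ahr (-0.46 ± 0.10), 5330434G04Rik (-0.39), Farp1 (-0.41), Wdcp (-0.52), Tmem267 (0.60), Cttnbp2 (-0.48), Ildr2 (-0.43), Cebpd (0.77), Prokr2 (-0.59 ± 0.15) and Bpgm (0.40), and none was called. Ntrk3 did not pass either (-0.31 ± 0.20). Prokr2 and Ahr had lain higher with CFA in WT, where DESeq2 called them and edgeR did not, and Prokr2 fell in KI against WT with CFA.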

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

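In this part, the tests on the Ntrk3 rise and the test with the muscle score were chosen only after the result they measure had been seen; the tests of depth, marrow and blood and the counts over other splits of the libraries were not.

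Among 76 groups of 4 libraries tested for a library standing apart, 6 did, where chance gives about 3.8, and 5 of them follow. In WT vehicle 4 the A-fibre score was 6.711 against 6.84 to 6.865 in the rest of its group, and the ion channel score was 6.573 against 6.811 to 6.839. In WT CFA 2 the A-fibre score was 6.889 against 6.798 to 6.807. In KI CFA 3 the proliferation score was 1.903 against 0.905 to 0.9599. In KI CFA 1 the immediate early score was 2.968 against 2.686 to 2.707.

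The response to CFA differed between the genotypes for 9 lists by camera at the preset correlation, and for none with an estimated correlation. Medians of the interaction were -0.76 for interferon-stimulated genes (camera adjusted p = 5.01e-14; adjusted p = 0.62 with an estimated correlation), -0.29 for antigen presentation genes (6.05e-07; 0.62), 0.22 for ribosomal proteins (1.21e-14; 0.62) and 0.19 for oxidative phosphorylation genes (3.49e-08; 0.62). They were -0.14 for ion channels (0.0054; 0.62), 0.18 for Schwann cell and myelin genes (0.0193; 0.92), 2.37 for neutrophil markers (0.00625; 0.79), 0.35 for proliferation genes (0.0359; 0.652) and 0.34 for immediate early genes (0.0054; 0.62). Without WT CFA 2 the interferon median was -0.35. Without WT vehicle 4 the ribosomal median was 0.10, the oxidative phosphorylation median 0.09 and the ion channel median -0.07, the last not called. Without KI CFA 3 the neutrophil median was 0.52 and the proliferation median 0.02, neither called. Neutrophil markers also lost the call without WT CFA 4 (2.21) or WT vehicle 4 (1.99), and immediate early genes without WT vehicle 1 (0.23). Proliferation genes also lost it without KI vehicle 3 (0.33), WT CFA 3 (0.36) or 4 (0.39) or WT vehicle 1 (0.40) or 4 (0.29). Schwann cell genes lost it without KI CFA 1 (0.12), KI vehicle 1 (0.07), WT CFA 3 (0.09) or WT vehicle 3 (0.09) or 4 (0.08), and had 0.28 without WT CFA 4.

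The first pattern is the rise of Ntrk3 in KI libraries (1.29 ± 0.103 over both injections). If only the cells that the A-fibre list marks expressed its members, an even gain of these cells would raise the other 14 about as much. Their median was 0.249 (bootstrap SE 0.127) and the largest was 0.931, which under that condition argues against such an even gain as the whole cause. Whether other cells of the ganglia express the members was not tested, and such expression would lower their rise. The list mixes kinds of A-fibre neuron, so a gain of only the cells that carry Ntrk3 was not tested. Higher expression of the Ntrk3 gene itself stays open. The counts do not show whether the added reads come from that gene or from the knock-in construct, since reads along the gene are not analysed here.

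The next pattern is the set of 673 genotype calls with vehicle. With the muscle score as a covariate, 330 of them kept an adjusted p under 0.05 (49.0%, 95% interval 45.2 to 52.9), while their median log2 change in the called direction went from 0.382 to 0.391 (103% kept) and 99.9% kept their sign. The median SE went from 0.0866 to 0.0966, and why calls ended was not tested. Of the calls, 94.4% had the same sign with CFA without KI CFA 2. Muscle scores were still 0.521 in KI CFA 3 and -1.62 in KI CFA 1, with -2.77 in KI CFA 4, against -2.75 to -2.61 in WT CFA. The share of equal signs therefore cannot decide about muscle. Muscle may account for the muscle transcripts, while the log2 change kept with the covariate argues against it for the whole set. The share of the log2 change was made the deciding value after both values had been seen, and the share of calls alone would have left the question open. After all libraries were thinned to the smallest total of 22742209 counts, 82.9% of the calls were kept (558, with 623 calls in all), which argues against depth. The knock-in itself stays an open explanation, and so does a structure among the WT libraries that is given under the other splits below.

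The last pattern is the neutrophil and erythroid signal of KI CFA 3. Ngp was at 69.4 CPM against at most 8.03 in the other 15 libraries, S100a9 at 77.5 against 9.04, Slc4a1 at 16.1 against 1.05 and Alas2 at 7.77 against 1.63. Granule genes of marrow progenitors (Elane, Mpo, Prtn3 and Ctsg) summed to 10.8 CPM against at most 1.3 elsewhere, which is consistent with bone marrow carried over during dissection and argues against blood alone. Haemoglobin genes had 0 counts in every library, so they decide nothing. No biological explanation was tested, since 1 library of the KI CFA group shows the signal and the design does not set it apart.

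Each count of called genes was compared with other splits of the same libraries. For KI against WT, the real split gave the most calls in each case. It was the 1 split of 35 with 673 calls with vehicle (highest other 15) and the 1 of 35 with 441 with CFA (highest other 0). For the mean it was the 1 of 100 drawn with 1390 (highest other 0). Chance is thus an unlikely account of these counts, and with 35 splits no share below 1 of 35 can be reached. The mixed splits also hold the genotype difference within their groups, which widens their spread and can lower their counts. For the mean effect of CFA, chance cannot be excluded, since 5 of 100 drawn gave at least its 4 calls (highest other 12). For CFA in WT, CFA in KI and the interaction the real count was 0, which all 35, 35 and 100 splits reach by definition, so the splits test nothing there (highest other 789, 52 and 6). The split with 789 calls set WT replicates 1 and 2 of both injections against replicates 3 and 4, and it points to a structure of the WT samples. It also parts the numbers in the labels' source names, 1 to 5 against 6 to 9, so an order or batch of collection stays possible. What the numbers stand for is not given in the labels. In KI, the split of source numbers 1 to 5 against 6 to 10 gave 15 calls. With the WT split as a covariate, CFA against vehicle in WT again had 0 calls.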

How the results depend on the processing

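The covariates, the surrogate variables and the fits without 2 or 6 libraries were chosen only after the results had been seen; the other alternatives were fixed before the data were examined. For 217 gene results, 6849 alternative values were computed: 6188 kept direction and side of the threshold, 602 fell short of it, 47 newly passed it and 12 reversed. For 42 list results, 1184 of 1237 kept both, 46 fell short and 7 reversed. The direction of a list is the one camera gave, which can differ from the sign of its median. These include genes taken by the naming rule that the text does not name. Calls of Ntrk3, Ngfr and Smr2 between genotypes held in all settings run. No scaling moved the median of all genes by more than 0.04.

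Counts of called genes moved as follows, and the cause was not tested except where fewer libraries or another threshold give it. Genotype counts with the WT split compare KI with the fitted level of WT replicates 1 and 2, not with the mean of all WT libraries. For KI against WT with vehicle (673) there were 214 genes with only the groups compared, 1721 at an adjusted p under 0.1, 156 at 0.01, 1476 by DESeq2, 349 with the muscle covariate, 99 without the 6 libraries with muscle (1 KI vehicle library is then left and is assumed to vary like the other groups), and 294 with the WT split as a covariate. With CFA (441) there were 198 at 0.01, 667 by DESeq2 and 187 with 2 surrogate variables. For the mean of both (1390) there were 2172 at 0.1, 630 at 0.01, 812 with the muscle covariate, 752 with 2 surrogate variables, 473 without 6 libraries and 828 with the WT split. For CFA against vehicle in WT (0) DESeq2 called 11 and limma-voom 1. In KI (0) there were 1 with only the groups compared, 15 by DESeq2 and 6 without 6 libraries. For the mean of both genotypes (4) there were 0 with library size only, 2 with no filter, 7 at 0.1, 0 at 0.01, 57 by DESeq2, 7 by limma-voom, 0 with the muscle covariate, 0 with 2 surrogate variables and 1 without 6 libraries. The interaction (0) gave 3 without 6 libraries. Leaving out 1 library gave 0 to 2 calls for CFA in WT, 0 to 53 for CFA in KI, 284 to 905 for genotype with vehicle, 241 to 652 with CFA, 993 to 1430 for its mean, 0 to 39 for the mean CFA effect and 0 to 0 for the interaction.

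The replicate numbers do not pair the libraries: the correlations of 24 same-numbered pairs ran from -0.207 to 0.133, 3 were over 0.1, and 2 of 16 libraries lay closest to their own number. The replicate block left 1 call for the mean CFA effect and moved no other count by over 1.5 times.

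Results that reversed (for lists, the camera direction), with the cause not tested unless given, included these. Ntrk3 with CFA in WT (0.15) ran from -0.01 without WT vehicle 4 to 0.27 without WT vehicle 1. The muscle covariate takes the muscle signal out by construction. With it the median of the muscle list went to -0.05 in KI, where only the camera direction reversed and the median kept its sign. Between genotypes with vehicle the list went to -0.15, and Myh2 went from 5.66 to -1.03. Without the 6 libraries the muscle list was 3.51 in KI, -1.85 between genotypes with vehicle and 0.69 for the mean CFA effect. There Acta1 was -0.57 between genotypes with vehicle, Pygm 0.16 and Myom2 0.41 with CFA in KI, and the oxidative phosphorylation list 0.01 between genotypes with vehicle and 0.00 in the interaction.

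In the simulated counts, changes of 0.32 on the log2 scale were recovered in 36% between genotypes with vehicle and with CFA, 30% for CFA in WT, 38% for CFA in KI and 8% in the interaction. In the 8 against 8 comparisons they were recovered in 64% between genotypes and 70% for CFA.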

Other observations

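No hypothesis was tested in this part, and the items were picked only after their values had been seen. Between genotypes over both injections, 3 of 15 clock genes rose, Nr1d1 (0.48 ± 0.11, edgeR adjusted p = 0.00785), Nr1d2 (0.27 ± 0.06, edgeR adjusted p = 0.0118) and Hlf (0.39 ± 0.10). Adjusted over the list alone 6 rose and 1 fell, and the list median was 0.15 (camera adjusted p = 0.00168; adjusted p = 0.0507 with an estimated correlation). All 3 lost the call with the muscle covariate (0.36 for Nr1d1, 0.24 for Nr1d2 and 0.35 for Hlf) and without the 6 libraries with muscle (0.33, 0.32 and 0.37), where the list lost it too (0.11). With 2 surrogate variables Nr1d2 (0.27) and Hlf (0.42) lost it. Hlf also lost it without KI CFA 1 (0.34) or 3 (0.37), without KI vehicle 4 (0.34), and without WT CFA 3 and WT vehicle 4 together (0.39). Of 7 markers of C-LTMR and cold neurons, Trpm8 fell (-0.35 ± 0.06, edgeR adjusted p = 0.00184), while Slc17a8 (0.35 ± 0.08) and Fam19a4 (0.22) rose. Slc17a8 and Fam19a4 lost the call with 2 surrogate variables (0.32 and 0.23), with the WT split as a covariate (0.34 and 0.25) and without the 6 libraries (0.33 and 0.19). Fam19a4 also lost it with the muscle covariate (0.20), without KI CFA 4 (0.20), KI vehicle 1 (0.20) or KI vehicle 3 (0.21), and without WT CFA 3 and WT vehicle 4 together (0.21). Of 12 MAPK feedback genes, Etv5 (-0.32 ± 0.05) and Spred3 (-0.35 ± 0.06) fell and Dusp5 rose (0.30 ± 0.07). Without the 6 libraries Spred3 (-0.38) and Dusp5 (0.26) lost the call, and Dusp5 also lost it with the WT split as a covariate (0.24).

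The axon injury score was 4.305 in WT CFA 1 and 4.22 in WT CFA 2, against 2.49 to 3.74 in the other 14 libraries. On the first principal component, KI vehicle 4 lay at 42.4, KI vehicle 1 at 36.7 and WT CFA 3 at -38.6, and on the second WT vehicle 4 lay at -42.3. With WT replicates 1 and 2 against 3 and 4 as a covariate, edgeR called 294 genes between genotypes with vehicle, 255 of them among the 673. It called 579 with CFA and 5 for the mean CFA effect. The 294 and 579 calls compare KI with the fitted level of WT replicates 1 and 2, not with the mean of all WT libraries.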
